A study of Mus musculus with 3 samples.

How the data were processed

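Gene expression was measured in 3 samples of ureteric duct cells from mouse embryos at 10.5 days post coitum (Theiler stage 18, CD-1 strain). Per the labels' protocols, the embryos carried a Hoxb7-GFP transgene, which marks the nephric duct and its derivatives with green fluorescent protein. The duct was dissected, dissociated with trypsin, and sorted by fluorescence. The labels give a pool of 1 duct per sample and describe the samples as not pooled. RNA was amplified in 1 round with a kit for picogram inputs, biotin-labelled and hybridised to a mouse Affymetrix array, 1 array per sample. The 3 samples form a single group numbered 1 to 3 in the titles, with no second group, so no difference between conditions was tested. Nothing in the labels says whether the samples came from separate embryos or litters. Each p-value therefore measures only the spread between these 3 samples, which may be technical.

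The deposited table holds 1 value for each of 35557 probe sets on each array. Its values, summarised by the authors, were read as log2 signals from their range, 1.90 to 14.2, and their medians of 5.85 to 5.90 per array. Affymetrix Expression Console is named in the submitters' processing notes. The algorithm, version, background correction and filters are not given in the sources used here. Of the probe sets, 14102 (39.7%) held exactly the same value on all 3 arrays. An SD of 0 therefore occurs for many genes, and array-to-array error is understated for them. Further genes were tied on 2 of the 3 arrays, and error may be understated for those as well. No scanner file was used here.

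Probe sets were named through the platform annotation. It gave a single symbol to 21789 probe sets and several to 1621, which were left out, and 12147 were unnamed here. Of the single-gene probe sets, 21698 matched the reference gene table of the GRCm38.p6 assembly by Entrez number, and 0 symbols changed. The single-gene probe sets covered 19938 genes, of which 999 had more than 1 probe set. A gene took its probe set with the highest mean. No genome build is named for the array, so no coordinates are given. Probe sets differ in affinity, and a single gene was therefore tested only against background. List medians and the genes named for high means are descriptions of these arrays and do not rank transcript amounts.

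Background was taken from 1212 probe sets for olfactory and vomeronasal receptor genes, which belong to sensory neurons. An array's cutoff was the 95th percentile of these probe sets, which came to 5.69, 5.73 and 5.70 log2 units on arrays 1, 2 and 3. By construction, about 5% of these receptor probe sets lie above it on each array. For other genes with no transcript in the tissue that share is not known, so the calls below have no known false rate. On these arrays, 57 receptor probe sets lay above the cutoff on all 3 arrays. The values minus the cutoff were fitted with an intercept in limma 3.58.1 (R 4.3.3) with empirical Bayes moderation. A one-sided p for a value above the cutoff was adjusted by Benjamini-Hochberg over the 21789 probe sets, and a gene with an adjusted p under 0.05 is called above background or said to pass. For a probe set with one value on all arrays, the fitted spread comes only from the differences between the 3 cutoffs and from moderation, so its p is too small. The moderation had 1.13 prior degrees of freedom and a prior SD of 0.035 log2 units. Without array 3, limma estimated one common spread for all genes, so calls from that fit ignore the spread of each gene and were not used for single genes. This test was checked on simulated data with 200 probe sets at known distances and a spread of 0.144 log2 units. It called 78% of those set 0.25 log2 units above the cutoff, 100% of those set 0.5 or 1 unit above it, and 0% of those set 0.5 units below it. Every simulated probe set had this same spread and none was tied. These shares therefore do not describe genes with larger spreads or tied values. They also do not give the error rate just below the cutoff. The number of arrays limits the precision.

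The gene lists (23 lists with 317 genes, 295 measured), the background test and the rule for named genes were fixed before the data were examined. List genes without a probe set of their own were not analysed here. The rule takes every measured gene of the duct, tip and sex chromosome lists, of every other list the 2 genes with the highest mean and the 1 with the lowest, the 10 genes with the highest means after leaving out ribosomal and mitochondrial genes, and the 10 genes above background with the largest range over the arrays. Hox genes are given as a family. A list's median was placed among the medians of 10000 random lists of as many genes, as a description of these arrays. As an alternative, its mean was placed among the means of random lists. A list's shift on one array, a comparison chosen after seeing the data, was placed among 10000 random lists matched on mean signal in 20 bins. These steps used Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6. The alternatives covered the 90th and the 99th percentile, olfactory receptors alone, the 30th percentile of all probe sets, quantile normalization, the mean of a gene's probe sets, a count of genes above the cutoff on all 3 arrays, a variance trend, and leaving out each array. A cutoff raised by 1 log2 unit and a spread for tied probe sets borrowed from untied ones were added after seeing the data.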

Results

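Transcript levels were profiled in Hoxb7-GFP-positive ureteric duct cells isolated at 10.5 days post coitum, the stage at which the ureteric bud forms from the nephric duct. The data comprised 3 arrays of one group, with a signal for 19938 genes. The question such a design addresses is which genes the sorted duct cells express, and each gene was set against the background of its array. In limma's one-sided test, 11203 genes (56.2%) lay above background at a Benjamini-Hochberg adjusted p under 0.05, and 8735 did not. At the 99th percentile of the receptor probe sets the count was 7190. Raising the cutoff by 1 log2 unit, chosen after seeing the data, gave 5653, and took the count over all lists from 196 to 110. Values are log2 signals, given as mean ± SD over the 3 arrays (n = 3), and "one value" marks genes whose deposited value was identical on all 3 arrays, where no spread can be given.

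All 18 measured genes of the nephric and ureteric duct list passed the test, and 18 passed adjusted over the list alone. Signals were 11.71 ± 0.03 for Calb1, a calcium-binding protein of the duct epithelium, 9.43 ± 0.20 for Gata3 and 8.79 ± 0.03 for Pax2, transcription factors required for the duct. Mecom read 10.26 (one value) from the brighter of its probe sets, and 7.08 from the other. Further transcription factors were Tfap2a at 8.22 (one value), Sim1 at 8.07 ± 0.05, Emx2 at 7.72 (one value), Grhl2 at 7.40 ± 0.24, Lhx1 at 7.04 ± 0.18, Pax8 at 7.01 (one value) and Sall1 at 6.99 (one value). Hoxb7, whose promoter drives the sorting transgene, read 7.32 (one value), 1.62 log2 units above the mean cutoff. The extracellular matrix protein gene Npnt read 7.82 ± 0.05, the kidney cadherin gene Cdh16 7.33 ± 0.20, and the secreted factors Wnt9b and Bmp7 6.96 (one value) and 6.83 ± 0.04. Sox8 at 6.04 and Wnt7b at 5.81, each with one value, also passed. These values were shared with genes of other lists: Wt1 and Nanos3 also read 6.03524, and Lef1 and Dll3 also read 5.81384. Whether such shared values are specific to the gene was not tested. The duct list's median of 7.37 lay at percentile 99.5 of 10000 random lists of as many genes. At the 99th percentile cutoff 16 of the 18 stayed above, and Sox8 and Wnt7b did not. Lhx1, Sox8 and Wnt7b did not pass with the cutoff raised by 1 log2 unit. The Wnt7b call also ended without array 1, with olfactory receptors alone as background, and with the spread of tied probe sets taken from untied ones.

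Of the tip and Ret signalling genes, 12 of 15 measured members were above background, and 12 adjusted over the list alone. Ret, the receptor tyrosine kinase for GDNF, lay 1.29 log2 units above the mean cutoff with an SD of 0.18 (limma, Benjamini-Hochberg adjusted p = 0.00075). Its co-receptor gene Gfra1 had a signal of 6.86 (one value). The chemokine receptor gene Cxcr4 read 8.06 ± 0.19, the ERK phosphatase gene Dusp6 7.84 ± 0.21, Sox9 7.75 (one value), Etv5 7.24 ± 0.02 and the orphan receptor kinase gene Ros1 7.19 (one value). Etv5 read 6.12 from its other probe set, below the mean 99th percentile cutoff of 6.38. Myb read 6.74 ± 0.24, Spry1, an inhibitor of receptor tyrosine kinase signalling, 6.52 ± 0.08 and Mycn 6.49 ± 0.14. The tip ligand gene Wnt11 at 5.99 ± 0.05 and Etv4 at 5.89 ± 0.02 lay within 0.29 log2 units of the mean cutoff. Mycn, Wnt11 and Etv4 did not pass at the 99th percentile. These genes, Ret, Myb and Spry1 did not pass with the cutoff raised by 1 log2 unit. Adamts18 at 5.51 (one value), Kif26b at 5.32 ± 0.04 and Slco4c1 at 3.43 (one value) did not pass. The list's median of 6.74 lay at percentile 92.4 of random lists, but its mean lay only at percentile 74.3.

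**Figure D1:**
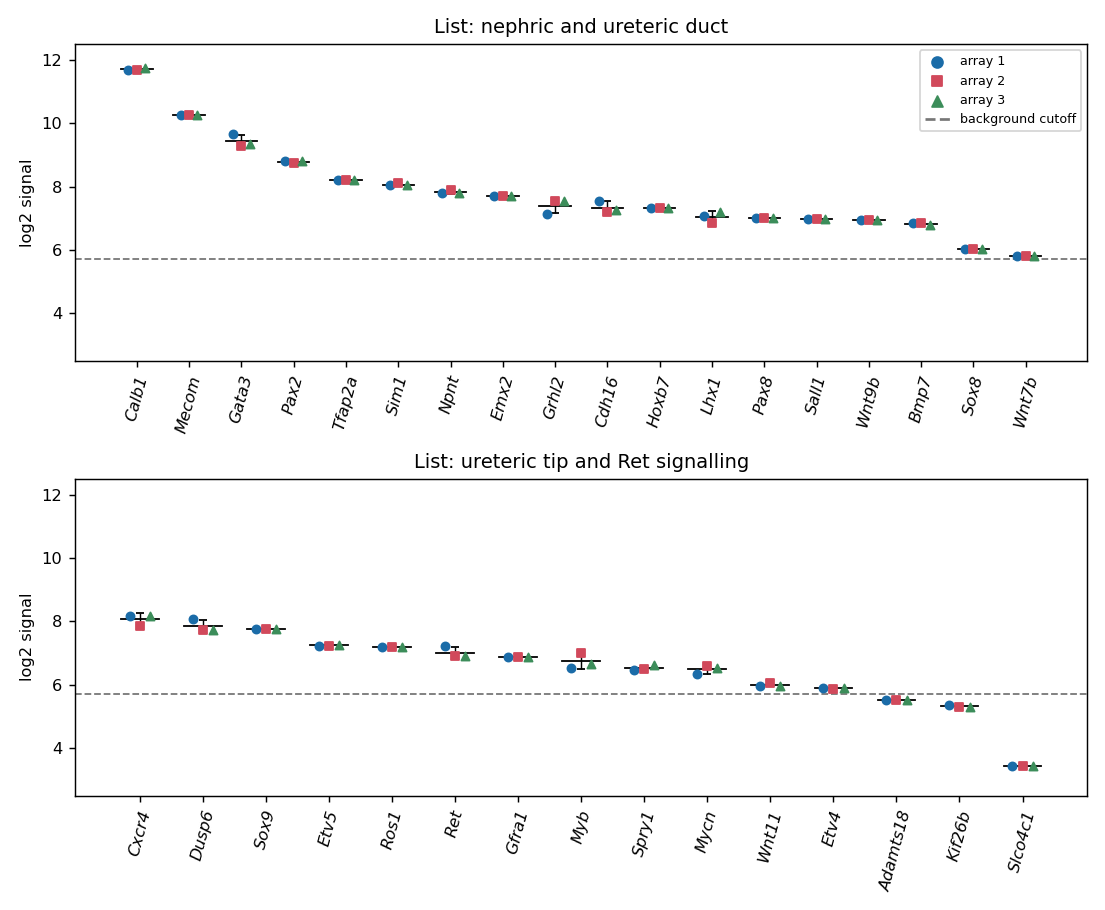
Log2 signal (vertical axis) of each measured gene of the duct list (upper panel) and of the tip and Ret signalling list (lower panel) on arrays 1, 2 and 3, with the mean as a bar and the SD over 3 arrays as whiskers; the dashed line is the mean background cutoff. All 18 duct genes and 12 of 15 tip genes passed the test.

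Epithelial genes passed in 21 of 23 cases, in 21 adjusted over the list alone, and in 18 at the 99th percentile. The simple-epithelium keratins Krt8 and Krt18 read 10.56 ± 0.37 and 9.77 ± 0.05. Krt19 at 5.41 (one value) did not pass. The list's median was 7.03, at percentile 98.98 of random lists. Genes of later duct and urothelial differentiation passed in 8 of 17 cases, or 47.1% against 56.2% of all genes, and in 4 at the 99th percentile. Adjusted over the list alone the count was 8. Hsd11b2, the cortisol-inactivating enzyme of mineralocorticoid target cells, read 7.20 ± 0.20 and the uroplakin gene Upk1a 6.75 ± 0.02. The terminal keratin gene Krt20 at 4.55 (one value) did not pass. For differentiated nephron segments, 7 of 14 passed, 7 adjusted over the list alone, and 1 at the 99th percentile, the endocytic receptor gene Lrp2 at 8.61 (one value). The organic anion transporter gene Slc22a8 read 6.41 and the claudin gene Cldn16 4.36, each with one value, and the second did not pass.

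In the metanephric mesenchyme list 4 of 13 measured genes passed, and 1 at the 99th percentile. This was Cited1, a transcriptional co-regulator of nephron progenitors, at 7.71 ± 0.17. Crym followed at 6.48 ± 0.05, and Meox2 was lowest at 4.47 (one value). Named after their values were seen, Wt1 at 6.04 (one value) and Gdnf, the ligand of Ret, at 5.80 ± 0.05 passed, and the nephron progenitor factor Six2 at 5.07 and Osr1 at 4.78, each with one value, did not. Wt1 held exactly the value of Sox8 in the duct list. The mesenchyme list's median of 5.18 lay at percentile 3.87 of random lists. In the stroma and fibroblast list 6 of 17 passed, with the intermediate filament gene Vim at 9.71 ± 0.40, Col1a1 at 6.75 (one value), and Lum at 3.23 (one value), which did not pass. The stromal count was 3 at the 99th percentile. Adjusted over each list alone the mesenchyme count was 4 and the stromal count 6.

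Of 14 endothelial genes, 13 passed over all genes and 14 adjusted over the list alone, and 12 passed at the 99th percentile. Emcn, an endothelial sialomucin, read 10.07 ± 0.69, and Cdh5, the vascular cadherin, 9.10 ± 0.58 (limma, Benjamini-Hochberg adjusted p = 0.0011). Sox17, at 5.80 ± 0.05, did not pass over all genes (limma, adjusted p = 0.062). The list's median of 7.40 lay at percentile 99.3 of random lists. These genes differed between arrays: 13 of the 14 were lowest on array 2. Their median was 7.02 on array 2, against 7.75 on array 1 and 7.72 on array 3, while the median of all named probe sets was 6.06, 6.06 and 6.04 on arrays 1, 2 and 3. The mean over the list on array 2 minus that of the other arrays was -0.67 ± 0.11 log2 units (SE over genes), below all 10000 level-matched random lists, whose lowest value was -0.49. On the same array the duct list gave -0.02 ± 0.03 and the dissociation stress list -0.26 ± 0.11 (SE over genes). Genes are not independent replicates, and array 2 is a single sample.

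In the macrophage and leukocyte list 1 of 13 passed, Cx3cr1 at 6.54 (one value). Cd68 at 6.31 ± 0.51 and Adgre1 at 4.09 (one value) did not. The value of Cx3cr1, 6.54302, was also read for Crym and Mycn on array 3. In the list of neurons and neural crest 2 of 9 passed, the neuregulin receptor gene Erbb3 at 6.96 (one value) and Sox10 at 6.40 ± 0.03, and Elavl4 at 4.13 (one value) did not. In the germ cell list 3 of 10 passed. Of these, Sall4 at 8.05 ± 0.06 and the stem cell factor receptor gene Kit at 6.93 (one value) are also known outside the germ line, while the germ cell helicase gene Ddx4 at 4.00 (one value) did not pass. In the gonad and coelomic epithelium list 4 of 8 passed, led by Tbx2 at 7.30 (one value) and Gata4 at 6.34 ± 0.08, while Lhx9 at 5.09 (one value) did not. In the red cell list 1 of 8 measured genes passed, Gata1 at 6.06 ± 0.05, named after its value was seen. The embryonic globin genes differed widely between arrays: Hbb-y read 10.02 on array 1 against 5.31 and 5.45 on arrays 2 and 3, and Hba-x 8.89 against 5.97 and 5.84. Neither passed, with SDs of 2.68 and 1.72, but Hba-x passed without array 1. Rhag read 3.97 (one value). Adjusted over each list alone, these counts were the same. At the 99th percentile 0 red cell, 1 gonadal and 1 neural gene passed, and without array 1 the red cell count was 2 and the macrophage count 2.

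**Figure D2:**
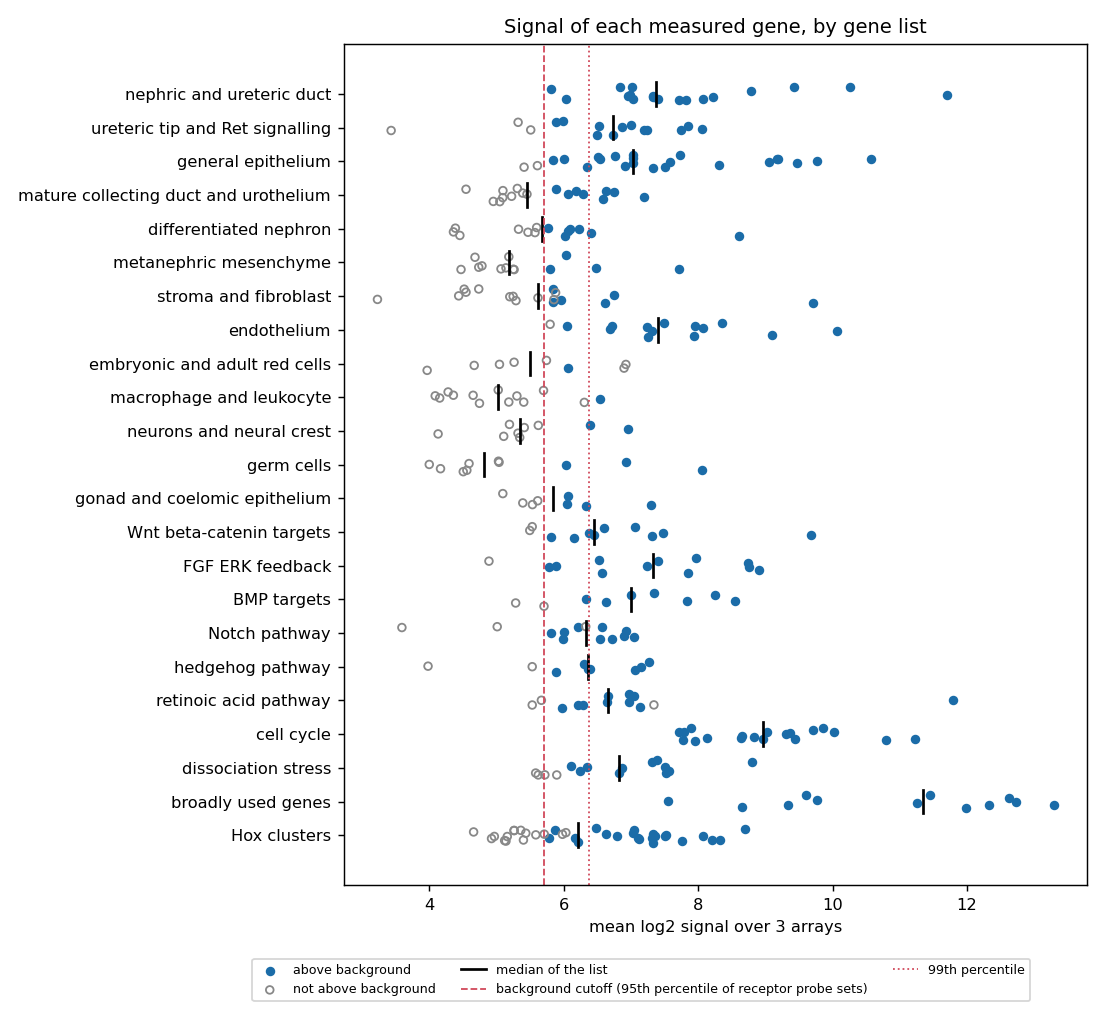
Mean log2 signal over 3 arrays (horizontal axis) of the measured genes of each gene list and of the Hox clusters, in rows by list. The sex chromosome list is left out. Filled points passed the background test, open points did not, and black bars are list medians. The dashed and dotted lines are the mean cutoffs of 5.71 and 6.38. The duct, epithelial, endothelial and cell cycle lists have medians to the right of both lines, and the mesenchyme, macrophage and germ cell lists to the left.

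Of 37 measured Hox genes, which set position along the body axis, 22 passed, or 59.5% against 56.2% of all genes. Adjusted over the family alone, 22 also passed. Of the 25 in paralogue groups 1 to 9, 21 passed, and of the 12 in groups 10 to 13, 1 did, Hoxd12 at 5.78 (one value). At the 99th percentile these counts were 17 and 0. The Hoxd12 call also ended without array 1, with olfactory receptors alone as background, and with the spread of tied probe sets taken from untied ones. The HoxB cluster passed in 8 of 9 cases, with Hoxb6 at 8.32 (one value), Hoxb4 at 8.21 ± 0.33 and Hoxb5 at 8.08 (one value). The HoxD cluster passed in 6 of 9, with Hoxd8 at 8.70 ± 0.32, the HoxA cluster in 5 of 10, and the HoxC cluster in 3 of 9. Hoxa11 at 5.14 and Hoxd11 at 5.26, each with one value, did not pass. Whether the groups differ was not tested. With the 30th percentile of all probe sets as the cutoff, 25 of 25 and 9 of 12 passed, 34 in all.

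The feedback genes of FGF and ERK signalling passed in 11 of 12 cases, with Spred2 at 8.90 ± 0.23 and Il17rd at 8.75 ± 0.0047, while Etv1 at 4.89 (one value) did not pass. Il17rd read 6.52 from its other probe set. The list's median of 7.33 lay at percentile 98.5 of random lists. Its members Etv4, Etv5, Spry1 and Dusp6 also belong to the tip and Ret signalling list. Targets of beta-catenin passed in 9 of 11 cases and in 4 at the 99th percentile. Ccnd1, the G1 cyclin, read 9.68 ± 0.20, the Wnt antagonist gene Dkk1 7.48 ± 0.14, and Notum 5.50 (one value), which did not pass. BMP target genes passed in 7 of 9, with the Id factors Id3 at 8.55 ± 0.13 and Id2 at 8.26 ± 0.25, and Msx2 not passing at 5.29 ± 0.02. Notch pathway genes passed in 10 of 13, in 11 adjusted over the list alone and in 6 at the 99th percentile, with Hes5 at 7.04 ± 0.0035, Notch1 at 6.92 ± 0.30, and Hey2 not passing at 3.59 (one value). Hedgehog pathway genes passed in 7 of 9 and in 3 at the 99th percentile, with the receptor gene Ptch1 at 7.26 ± 0.16 and Smo at 7.15 ± 0.07, and Hhip not passing at 3.98 (one value). Retinoic acid genes passed in 10 of 13 and in 6 at the 99th percentile. Crabp2, a retinoic acid-binding protein, read 11.79 ± 0.28. Crabp1, at 9.30 on array 1 and 6.39 and 6.33 on arrays 2 and 3, lay above the cutoff on each array but did not pass with its SD of 1.70, and it passed without array 1. The retinoic acid-degrading enzyme gene Cyp26a1, at 5.53 (one value), lay below the cutoff. The counts over these lists alone were otherwise those over all genes. Of all genes, 56.2% passed, and 7190 of 19938 did at the 99th percentile. Among random lists, the medians lay at percentile 78.2 for beta-catenin targets, 92.55 for BMP, 72.8 for Notch, 71.4 for hedgehog and 88.0 for retinoic acid. By their means, in the same order, the lists lay at percentiles 83.0, 90.3, 41.7, 50.4 and 92.45.

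All 19 measured cell cycle genes passed, and 19 also passed at the cutoff raised by 1 log2 unit. Pcna, the sliding clamp of DNA replication, read 11.23 ± 0.19 and Top2a 10.79 ± 0.32, although a second Top2a probe set read 3.51. Mcm7, a subunit of the replicative helicase, read 7.71 ± 0.18. All 12 measured broadly used genes passed, among them Tbp at 7.54 ± 0.19, Actb at 12.73 ± 0.46 and Eef1a1 at 13.29 ± 0.11. Genes known to respond to tissue dissociation passed in 11 of 15 cases, with Jun at 8.80 ± 0.48 and Egr1 at 7.57 ± 0.57, and Atf3 not passing at 5.58 (one value). The mean of this stress list was 6.95 on array 1, 6.58 on array 2 and 6.74 on array 3. The counts were the same adjusted over each list alone. The rule for named genes also took, for their mean signals, Baiap2l1 at 13.45 ± 0.24, Tmsb10 at 13.41 ± 0.06, Gas5 at 13.36 (one value), Tpt1 at 13.18 (one value), Cox6c at 13.05 ± 0.09, Calm2 at 12.97 (one value), Srsf3 at 12.95 ± 0.01, H2az1 at 12.86 ± 0.14 and Hmgn2 at 12.75 ± 0.20. These signals do not rank transcript amounts, since probe sets differ in affinity, and the other Baiap2l1 probe sets read 11.57 and 6.22. The other Gas5 probe sets read 10.61, 8.88 and 8.77, and the lowest Hmgn2 probe set read 8.73.

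The arrays agreed closely across genes, with Pearson's r of 0.9902 for arrays 1 and 2, 0.986 for arrays 1 and 3, and 0.986 for arrays 2 and 3; these are correlations across genes, which are not independent replicates. One value on all 3 arrays was held by 50.8% of genes, and the median SD of the others was 0.111 log2 units. These others, called untied, include genes tied on 2 arrays, since 58.4% to 62.6% of genes held one value on a given pair of arrays. Il17rd, for example, read 8.75461 on arrays 1 and 2 and 8.74641 on array 3. Small SDs may therefore understate the spread as well, and the ties may raise the correlations. A range over 1 log2 unit was found for 628 genes. Among genes above background, the largest ranges belonged to Phc3, which read 6.54 on array 3 against 9.10 and 9.59, and to Cd99l2, Ltn1, E2f3, 5730408K05Rik, Snord95, Guk1, Snora41, Get1 and Snord49b, with SDs between 1.22 and 1.64. Ltn1 read 7.66, 8.95 and 10.30 on arrays 1, 2 and 3, from the brightest of its 16 probe sets. Of these 10 genes, 7 lost their call without array 2 (all but E2f3, Guk1 and Snord49b), and E2f3 lost it without array 1. All 10 lost it with the cutoff raised by 1 log2 unit, and Cd99l2, E2f3, Snora41 and Snord95 at the 99th percentile and with olfactory receptors alone.

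Genes of the sex chromosomes were measured because the labels leave the embryos' sex open. The Y-linked genes Kdm5d at 7.83 ± 0.36, Eif2s3y at 7.33 ± 0.23, Sry at 6.81 ± 0.0023 and Uty at 6.70 ± 0.35 passed. Zfy1 at 3.15 ± 0.03 and Zfy2 at 3.42 ± 0.10 did not. Xist, the RNA of the inactive X chromosome, read 7.81 on array 1 and 7.69 on array 3 but 4.82 on array 2, and did not pass over the 3 arrays (limma, Benjamini-Hochberg adjusted p = 0.227), but passed without array 2. The count of 4 of 7 was the same adjusted over the list alone.

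**Figure D3:**
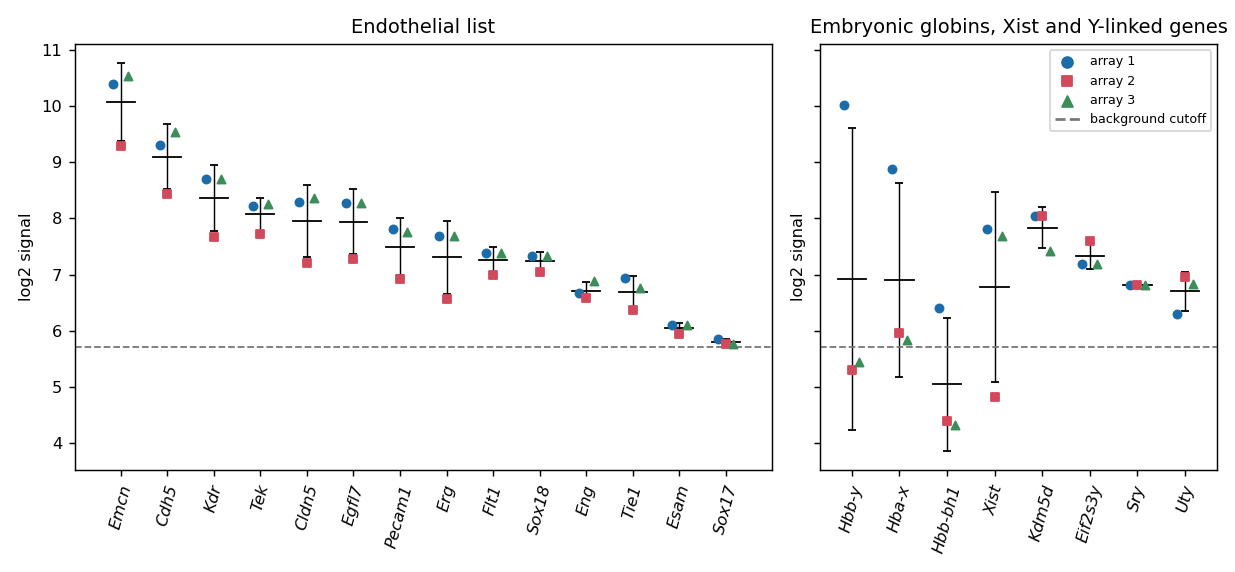
Log2 signal (vertical axis) on arrays 1, 2 and 3 of the 14 endothelial genes (left) and of embryonic globins, Xist and Y-linked genes (right), with the mean as a bar, the SD over 3 arrays as whiskers and the mean background cutoff as a dashed line. Array 2 is lowest for 13 of 14 endothelial genes and for Xist (4.82), and array 1 stands above the others for the globins.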

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

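The arrays' signal over background limits these results, since the count of genes above background depends on the cutoff: it was 11203 as reported, 7190 at the 99th percentile of receptor probe sets, 13047 at the 90th, and 5653 with the cutoff raised by 1 log2 unit, an alternative chosen after seeing the data. Leaving out an array gave 10364 to 11008, where the lowest comes from the fit without array 3. That fit gave all genes one spread, so its counts and calls do not measure how far the results rest on array 3. At the 99th percentile, counts fell by more than 1.5 times for these lists: mature duct 4, nephron 1, metanephric mesenchyme 1, stroma 3, red cells 0, neurons 1, gonad 1, beta-catenin targets 4, Notch 6, hedgehog 3 and retinoic acid 6. With the cutoff 1 unit higher they fell to 110 over all lists, 6 for tip genes, 13 for epithelium, 8 for endothelium, 7 for FGF feedback, 5 for dissociation stress, 3 each for beta-catenin targets, hedgehog and retinoic acid, 2 for Notch, 1 each for mature duct, nephron, mesenchyme, stroma, neurons and gonad, and 0 for red cells and macrophages. With the 30th percentile of all probe sets they rose to 34 Hox genes, 15 mature duct, 12 stroma, 11 nephron, 8 each for mesenchyme, neurons and gonad, 6 macrophage and 4 red cell genes. At the 90th percentile macrophage genes numbered 3 and red cell genes 2, and counting genes above the cutoff on all 3 arrays gave 2 and 3. Leaving out an array gave 3 to 8 stromal, 1 to 3 red cell and 1 to 2 macrophage genes; the 3 stromal and 3 red cell genes come from the fit without array 3. The duct count stayed between 15 and 18 and the cell cycle count at 19 under all settings run. The median SD of untied genes was 0.129 among genes above background, 0.0467 after quantile normalization, which breaks ties, and 0.108 to 0.120 without an array. Genes with one value came to 40.6%, 0.0050% and 58.4% to 62.6% in the same order. The lowest correlation was 0.975 among genes above background. Of the single-gene levels and list percentiles, 549 stayed within the spread between arrays and 70 moved further. This tally does not measure stability, since leaving out 1 of 3 arrays cannot move a mean by its SD. Of the levels of 119 named genes, 0 moved on leaving out an array, though the largest shift was 1.55 log2 units. The mean of a gene's probe sets moved 14, with a largest shift of 3.64, and quantile normalization 40, with a largest shift of 0.0475. Single-gene calls did change: of 91 named genes above background, 29 did not pass with the cutoff raised by 1 log2 unit and 14 did not at the 99th percentile. The 29 included Lhx1, Ret, Myb, Spry1, Notch1, Egr1, Upk1a, Col1a1 and Cx3cr1, and the 14 included Crym, Sox10, Gata4, Uty and Slc22a8. With the spread of tied probe sets taken from untied ones, also chosen after seeing the data, 10962 genes passed and the calls of Wnt7b, E2f3 and Snora41 ended; olfactory receptors alone ended 5 calls and quantile normalization those of E2f3 and Snora41. Leaving out array 1 ended 2 calls and added Hba-x, Cd68 and Crabp1, and leaving out array 2 ended 7 and added Xist. The cause of these changes was not tested. No paired analysis was possible because there is a single group.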

Other observations

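The families and the second endothelial list here were chosen after the data were examined, as were the tests of a floor, of a repeated library, of array scale and of the sex chromosome genes; the tests of median polish and of the second endothelial list were written before their results were seen. Frizzled receptors for Wnt ligands passed the background test in 9 of 10 cases, with Fzd4 at 8.95 ± 0.12, Fzd3 at 8.34 ± 0.07 and Fzd7 at 8.24 ± 0.14 (SD, n = 3). Of 19 Wnt ligands 9 passed, or 47.4% against 56.2% of all genes, and 3 did at the 99th percentile, led by Wnt4 at 7.44 and Wnt9b at 6.96. All 4 FGF receptor genes passed, with Fgfr2 at 8.74 ± 0.0092 and Fgfr1 at 7.41, against 6 of 22 genes with an Fgf symbol. At the 99th percentile these counts were 2 and 2. The 22 genes were taken by symbol and include Fgf11, Fgf12, Fgf13 and Fgf14, intracellular proteins rather than secreted ligands, which did not pass. Basement membrane genes included Lamb1 at 9.46 and Lamc1 at 9.16 among 8 of 10 laminins, and Col4a1 at 7.13 and Col4a2 at 6.88 ± 0.03 among 5 of 6 collagen IV genes, and 8 of 9 fibrillar collagens passed as well. At the 99th percentile 5 laminins, 2 collagen IV genes and 5 fibrillar collagens passed. The tight junction claudins passed in 13 of 23 cases, or 56.5% against 56.2% of all genes, with Cldn8 at 10.39 ± 0.34 and Cldn7 at 9.47 ± 0.48. At the 99th percentile 9 claudins passed, where 7190 of all 19938 genes did. Of the taste and trace amine receptors 1 of 44 passed and of the beta protocadherins 2 of 22, but of the keratins 14 of 48, among them Krt82, Krt34 and Krt72. Of these families, 0 receptors, 0 beta protocadherins and 5 keratins passed at the 99th percentile, with Krt8, Krt18, Krt7 and Krt87 among the 5.

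Of the probe sets, 39.7% hold exactly one value on all 3 arrays. A floor under low values as the whole cause is argued against by the 9.97% of the 1866 probe sets with a mean over 10 log2 units that are tied as well, although 49.8% of those with a mean under 6 are tied, so a contribution of low values stays open. A copied array file is argued against by 234 genes that lie over 1 log2 unit apart in the closest pair of arrays. That count cannot tell whether a single library was hybridised more than once, since the spread between such hybridisations was not measured. A candidate explanation is summarisation by median polish over these 3 arrays. In simulated noise, this gave one value in 44.2% of probe sets of 11 probes and 79.2% of those of 25, but in 0% of those of 4, and with 4 or 9 arrays in 0% at each size, but with 5 arrays in 15.9% for 25 probes. The simulation was not matched to the number of probes per probe set on this array, and it did not vary signal level. It also did not model values shared between genes. Among genes, one value was held by 67.3% of those with means up to 5 and 14.9% of those over 10. The simulation therefore cannot decide how much of the pattern median polish accounts for. No biological explanation was tested.

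Endothelial genes lay above background and were lowest on array 2. In a second list of 28 endothelial genes, 24 passed, and of the 21 that passed and differed between arrays 18 (85.7%) were lowest on array 2, which is consistent with endothelial cells among the sorted cells in a share that differed by array; Aplnr read 9.45 on array 2 against 10.88 and 10.68 on arrays 1 and 3. The deposited values showed no lower scale of array 2: level-matched random lists moved by a median of -0.0111 log2 units and the duct list by -0.02. With 50.8% of genes holding one value and nearly equal array medians, the random lists could hardly move far from 0. They therefore cannot decide on the scale of array 2 before the values were summarised. The dissociation stress list was also lower on array 2, at -0.26 ± 0.11 (SE over genes), and so were Vim, at 9.24 against 9.94 on each of the other arrays, and Cited1, at 7.52 against 7.77 and 7.85. The lists that hold Vim and Cited1 moved less on array 2. The stroma and fibroblast list gave -0.04 ± 0.05 and the metanephric mesenchyme list -0.03 ± 0.02 (SE over genes). Sorting on GFP should remove endothelial cells, and how many of these genes duct cells themselves express is not known from these data. Expression of these genes by duct cells that varied between samples stays open, untested.

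Xist and Y-linked genes appeared on the same arrays. On 2 arrays, 1 and 3, Xist and at least 3 Y-linked genes lay more than 0.5 log2 units above the cutoff. This count restates the pattern and so does not bear out cells of both sexes on an array, which stay open, while the labels give 1 duct per sample, not pooled. Y-linked probe sets reading other transcripts, such as X-linked relatives, cannot be told apart from this, because the Y-linked genes above background were only 0.28 log2 units lower on arrays 1 and 3 (difference -0.28) and no array is known to be female. The absence of Xist signal on array 2 does not depend on that.

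The embryonic globins Hbb-y, Hba-x and Hbb-bh1 were higher on array 1 than on the other arrays, at 10.02, 8.89 and 6.41, and Crabp1 at 9.30 shared that pattern. The dissociation stress list was also higher on array 1, by 0.29 ± 0.09 (SE over genes), at percentile 99.88 of matched random lists. The epithelial list gave 0.16 ± 0.06 there, at percentile 97.93. Among the unnamed probe sets, 4409 of 12147 lay above the cutoff on all 3 arrays. Of 75 list-by-array shifts computed, 6 lay under percentile 1 of matched random lists and 7 above percentile 99, the endothelial, red cell and stress lists among them.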
